A study of Mus musculus with 92 samples.

How the data were processed

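The series holds Smart-seq2 libraries of single blastomeres taken from 8-cell mouse embryos (C57BL/6N, wild type) that had been microinjected at the zygote stage. The injected material was let-7d (Let7d), let-7e (Let7e), a microRNA named mi699a-5p in the labels, or a negative control (NC). Smart-seq2 amplifies full-length cDNA from one cell and attaches no molecular identifiers, so counts are reads and include amplification copies. The labels describe 92 cells, of which 82 have a column in the deposited tables. The other 10 were not analysed here.

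The deposited counts are raw read counts per gene and cell, per the labels and the values, which are whole numbers with column sums that differ between cells. The deposited RPKM values were made by the authors from the same libraries. STAR and the mouse build GRCm38.p6 are named per the submitters' processing notes, without versions, and the program that counted reads is not stated. By its name each table was filtered by the authors on CPM (reads of a gene scaled to a common library total), at a threshold that is not stated, and holds 7886 genes. Of the versioned gene identifiers, 7878 matched a symbol in GENCODE M21, 7657 of them with the same version, and 8 had none. All columns could be mapped, with 0 left over.

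The gene length implied by each RPKM value and its count was checked. For one gene the largest implied length exceeded the smallest across cells by a median factor of 223.7, lengths in neighbouring columns had a correlation of 0, and they repeated down the columns with a period of 55487 values (r = 0.996 at that lag). Zeros fell at the same places in both tables for 100% of values. The RPKM table was therefore read only as an alternative, and its values of one gene are not on one scale between cells.

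Columns were compared in pairs by the chi-square statistic per gene, over genes with a summed count of at least 20. One pair out of 3321, both from Let7d mouse id 2, gave 1.05 per gene over 6197 genes, against 28.7 for the next smallest pair and a median of 73.9 for cells of one mouse id. These columns were summed and counted as 1 cell, which left 81 cells. No cell fell below 25% of the median total or 50% of the median number of genes, and 0 cells were removed.

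Cells are not replicates. Counts were summed over the cells of each mouse id named in the labels, which gave 3 NC, 3 Let7d, 4 Let7e and 4 mi699a-5p values, called replicates 1 to 4 of their group by the number in the id. The labels do not say whether a mouse id is an embryo, a dam or a donor, so p-values of single genes and of permutation tests measure the spread between these mouse ids. Each group has its own mouse ids, and the same well names recur from group to group, so groups may have been handled apart. Any batch that coincides with the groups cannot be told apart from the injected material. Summed counts ranged from 6329464 to 24037593 reads.

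Differential expression was tested with edgeR 4.0.16 in R 4.3.3. TMM normalization, filterByExpr (which removed 0 genes) and the quasi-likelihood F test were used in 1 fit of all 4 groups, with 10 residual degrees of freedom and a common dispersion of 0.249. There were 6 contrasts: each injected microRNA against NC, Let7e against Let7d, and the mean of Let7d and Let7e against NC and against mi699a-5p. Tests were two-sided and adjusted by Benjamini-Hochberg at 0.05. CPM values are scaled by the TMM factors, and log2 CPM used a prior count of 2. Errors beside log2 fold changes are standard errors.

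Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry tests the members against no change rather than against the other genes. The effect given for a list is the mean log2 fold change of its members minus that of the other genes. Camera sets members against the other genes, so its p-values at the preset correlation do not measure the spread between mouse ids. That spread is given by the standard error of a list effect, which exceeded some called effects. Members above and below 0 are counted on the mean log2 CPM that camera used, and counts by the edgeR fold changes of single genes are given where they are lower by 2 or more members of a called list. The lists, written before the data were examined, were let-7 targets from the literature, miRNA processing and effector proteins, nuclear and mitochondrially encoded subunits of oxidative phosphorylation (OXPHOS), mitochondrial and cytosolic ribosomal proteins, pyruvate dehydrogenase and the TCA cycle, mitochondrial biogenesis, dynamics and import, fatty acid oxidation, glycolysis, maternal transcripts, 2-cell and early genome activation genes, pluripotency and inner cell mass markers, trophectoderm markers, G2/M and S phase genes, p53 response, integrated stress response, heat shock proteins, interferon response, cumulus and granulosa markers, sperm transcripts, blood, skin and stromal markers, and Y-linked genes. Lists with fewer than 5 measured members were reported as levels. Members were also adjusted over their list alone. That does not correct for the number of lists and comparisons, so some of these calls can come by chance.

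A let-7 seed match was searched in the longest annotated 3' untranslated region (UTR) of each gene: CTACCTCA (8mer), CTACCTC (7mer-m8) or TACCTCA (7mer-A1). Of 7560 genes with an annotated 3' UTR (95.9%), 1285 held a site and 286 an 8mer. Genes with a site were compared with those without by camera and by a score per mouse id. The matched form of the score compared genes within 5 bins of UTR length and 5 bins of expression. Scores and blastomere quality measures were compared by exact two-sided permutation tests over mouse ids, adjusted over 36 quality tests. With 3 against 3 mouse ids these cannot go below 0.1.

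The named genes were chosen by a rule. Among genes past the threshold with at least 10 CPM and all treated mouse ids on one side, it took up to 10 per direction. It added up to 4 members of each list with the smallest p, and always Dicer1, Lin28a, Hmga2 and Trim71. Where fewer than 3 genes passed in a direction, the 3 with the smallest p are given as values.

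Alternatives were RLE normalization, DESeq2 1.42.0, a minimum of 10 CPM (7272 genes), a replicate block, only the groups compared in the fit, all cells thinned to 1896018 reads (73 cells kept, with 6 of mi699a-5p and 2 of NC left out as shallower), no genes of chromosomes X and Y, the Y-linked level as a covariate, only mouse ids with at least 7 labelled cells, limma on log2(RPKM + 1), medians over cells for the quality measures, 8mer sites alone, no low-count filter, and leaving out each mouse id. Added after seeing the data were splitting the mouse ids that hold both Xist-carrying and Y-carrying cells, leaving out ribosomal RNA genes together with ENSMUSG00000118642.1, a gene of no annotated type, and simulated NC libraries. A cell was called Xist-carrying at 50 CPM of Xist and Y-carrying at 20 CPM over 4 Y-linked genes.

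The test was tried on simulated data with the group sizes of Let7d and NC. Over 5 draws it recovered 8.6% of genes changed 2-fold and 47.8% of those changed 4-fold, with 3.8 false calls per draw. A simulated shift of -0.6 in the list of 76 mitochondrial ribosomal protein genes was called in 5 of 5 draws and 0 other lists were called. Genes were drawn independently of each other, so this says nothing on false list calls that come from correlation between members. It also says nothing on lists with fewer members, in which no shift was simulated. Scores, permutation tests and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.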

Results

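Single blastomeres of 8-cell embryos were profiled to ask how let-7d and let-7e, injected into the zygote, alter early gene expression, in a study concerned with let-7, mitochondrial function and inherited metabolic traits. The NC group held 22 cells from 3 mouse ids, Let7d 18 cells from 3, Let7e 20 cells from 4 and mi699a-5p 21 cells from 4, with 2 to 8 cells per mouse id. A cell carried 1575609 to 4950404 reads (median 2736612) and 5562 to 7497 detected genes (median 6965). Cells of one mouse id resembled each other more than other cells, with a mean correlation of 0.075 against -0.01 for other mouse ids of the group and -0.02 for other groups. Both kinds of cells, carrying Xist or Y-linked transcripts, occurred within 1 mouse id of NC, 1 of Let7e and 1 of mi699a-5p. Xist-carrying cells alone made up 2 of the 3 Let7d mouse ids and 1 of mi699a-5p, while 1 Let7d, 3 Let7e, 2 NC and 2 mi699a-5p mouse ids held Y-carrying and no Xist-carrying cells, 1 of the mi699a-5p ones with 1 cell that carried neither.

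Quality measures of the blastomeres were compared between groups, and 0 of the 36 tests adjusted together passed. The 7 measured mitochondrially encoded OXPHOS genes took 3.82% ± 0.34 (SD, n = 3) of NC reads, 2.4% ± 0.52 (n = 3) of Let7d reads, 4.09% ± 1.28 (n = 4) of Let7e reads and 3.87% ± 1.01 (n = 4) of mi699a-5p reads. All 3 Let7d mouse ids lay below every NC mouse id, for which the exact permutation test gives p = 0.1, the smallest it allows (adjusted p = 0.45). Total reads per cell averaged 2526101 in NC, 3395103 in Let7d, 3004148 in Let7e and 2216581 in mi699a-5p. All 3 Let7d mouse ids lay above every NC mouse id in depth (exact permutation p = 0.1, adjusted p = 0.45). So did all 4 of Let7e (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.343). The 7 let-7 mouse ids were deeper than the 4 of mi699a-5p by an exact permutation p of 0.00303, the smallest possible, which did not pass adjustment (adjusted p = 0.109). Ribosomal RNA genes, which were CT010467.1 and the mitochondrially encoded mt-Rnr1 and mt-Rnr2, took 12.9% ± 3.24 of NC reads and 5.97% ± 2.57 of Let7d reads (exact permutation p = 0.1). The 50 most abundant genes took 27.2% of NC reads and 19.8% of Let7d reads, with all 3 Let7d mouse ids below every NC mouse id (exact permutation p = 0.1). The mitochondrially encoded share is thus not the only measure that separated Let7d from NC. Detected genes averaged 6965 in NC, 6890 in Let7d, 6941 in Let7e and 7002 in mi699a-5p, within the spread between mouse ids. The mean correlation between blastomeres of one mouse id was 0.0722 in NC, 0.088 in Let7d, 0.0768 in Let7e and 0.0695 in mi699a-5p, with exact permutation p-values from 0.5 to 0.943.

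**Figure D1:**
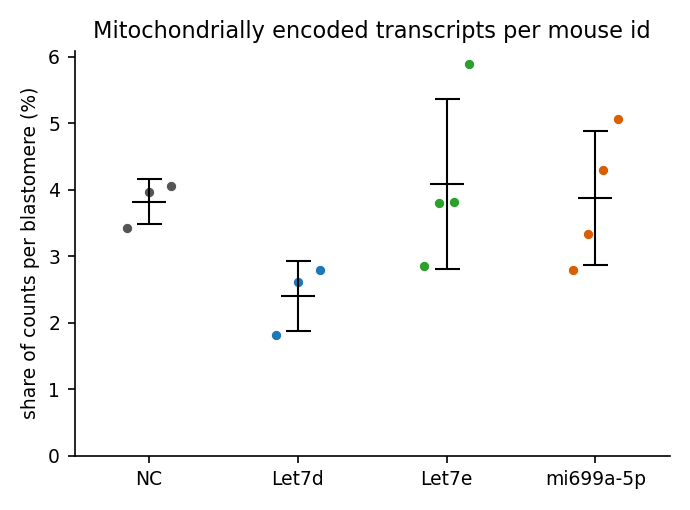
Share of reads from the 7 mitochondrially encoded OXPHOS genes (%, y axis) by injected group (x axis); each point is the mean over the blastomeres of one mouse id, with the group mean and SD. The 3 Let7d points lie between 1.81% and 2.80%, below the lowest NC point at 3.43%.

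In Let7d against NC, camera at the preset correlation called 4 lists, and 0 with an estimated correlation. Mitochondrially encoded OXPHOS transcripts and p53 response genes were lower, and G2/M genes and trophectoderm markers higher. The mitochondrially encoded list decreased by 0.75 ± 0.26 on the log2 scale, with 7 of 7 members below 0 (camera, adjusted p = 4.64e-06, and adjusted p = 0.335 with an estimated correlation). Adjusted over the list alone 7 of its 7 members changed, and 0 changed over all genes. The complex I subunit genes mt-Nd2 and mt-Nd1 had log2 fold changes of -0.98 ± 0.29 and -0.78 ± 0.27, mt-Co1 of complex IV -0.81 ± 0.27 and mt-Cytb of complex III -0.75 ± 0.30. Mt-Nd2 went from 3130 CPM in NC to 1590 CPM. Their nuclear-encoded partners, 75 OXPHOS genes, gave -0.09 ± 0.25 (camera adjusted p = 0.168), and 76 mitochondrial ribosomal protein genes gave -0.10 ± 0.16 (camera adjusted p = 0.114). Mean reads per cell were higher and the mean ribosomal RNA share lower in the Let7d group, as given above.

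The p53 response list decreased by 1.06 ± 0.50, with 16 of 17 members below 0 (camera, adjusted p = 1.41e-05, and adjusted p = 0.335 with an estimated correlation). Its members with the smallest p were Perp at -1.40 ± 0.43, Phlda3 at -2.38 ± 0.86, the cyclin-dependent kinase inhibitor gene Cdkn1a at -0.98 ± 0.36 and Ccng1 at -1.70 ± 0.68. Adjusted over the list alone 0 of them changed. Scores of this list were lowest in mouse ids made up of Xist-carrying cells, at -2.07 in Let7d replicate 2, -1.45 in mi699a-5p replicate 1 and -0.95 in Let7d replicate 3. With the Y-linked level as a covariate the Let7d effect was -0.27 (camera adjusted p = 0.442), and without Let7d replicate 2 it was -0.55 and still called (adjusted p = 0.0185).

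Trophectoderm markers rose by 0.63 ± 0.32 in Let7d, with 10 of 13 above 0 (8 of 13 by edgeR; camera, adjusted p = 0.0274, and adjusted p = 0.335 with an estimated correlation). The endocytic receptor gene Lrp2 had a log2 fold change of 2.27 ± 0.60, the only member to change when adjusted over the list alone (adjusted p = 0.0167). Fgfr2 gave 1.29 ± 0.45 and Dab2 1.14 ± 0.43. The G2/M list rose by 0.24 ± 0.16, with 19 of 25 above 0 (camera, adjusted p = 0.0184, and adjusted p = 0.433 with an estimated correlation). The spindle checkpoint kinase genes Bub1, at 1.07 ± 0.30, and Bub1b, at 1.25 ± 0.37, were its 2 members changed when adjusted over the list alone, and Kif20a gave 0.75 ± 0.32. Both calls ended without Let7d replicate 1 (adjusted p = 0.121 for each, effects 0.53 and 0.19) and without NC replicate 1 (0.71 with adjusted p = 0.0561, and 0.15 with adjusted p = 0.215). The trophectoderm call also ended without NC replicate 3 (0.23, adjusted p = 0.298), and without NC replicate 2 its effect was 0.95. With the mouse ids of both kinds of cells split, both ended (trophectoderm 0.53, adjusted p = 0.0691, and G2/M 0.13, 0.121), and with the Y-linked level as a covariate the trophectoderm call ended (0.58, 0.0716).

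Over all genes 1 changed in Let7d against NC by edgeR, downwards, with 370 genes at an unadjusted p under 0.05 where chance gives 394.3, and 3 by DESeq2 (this gene, Myo5b and Tug1). The gene, ENSMUSG00000118642.1, has no symbol, gene type or position in the annotation used. It had 197 CPM ± 69.3 (SD, n = 3) in NC, 31.3 ± 13.9 (n = 3) in Let7d, 86.2 ± 6.29 (n = 4) in Let7e and 48.8 ± 21.4 (n = 4) in mi699a-5p. Its log2 fold change in Let7d was -2.66 ± 0.40 (adjusted p = 0.0287). The call ended in 6 of 11 other settings, and without Let7d replicate 1 (adjusted p = 0.196), Let7d replicate 3 (0.228), NC replicate 1 (0.073) or NC replicate 3 (0.286), with fold changes of -2.33 or below in each. Limma on log2(RPKM + 1) is among the 6, and its loss says nothing, as RPKM values of one gene are not on one scale between cells. Among genes that did not pass, the smallest p were those of the long noncoding RNA Tug1 (1.29 ± 0.28), the nuclear export factor gene Cse1l (0.96 ± 0.23) and the mitochondrial elongation factor gene Gfm1 (1.29 ± 0.33). In the other direction were Rbm26 (-1.18 ± 0.31) and the ribosomal RNA gene CT010467.1 (-1.40 ± 0.38), located on chromosome 17 of GRCm38 from 39846353 to 39848827. Pdha1, the X-linked gene of a pyruvate dehydrogenase subunit, gave 0.96 ± 0.29, and Tarbp2, a cofactor of Dicer, -1.02 ± 0.31.

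**Figure D2:**
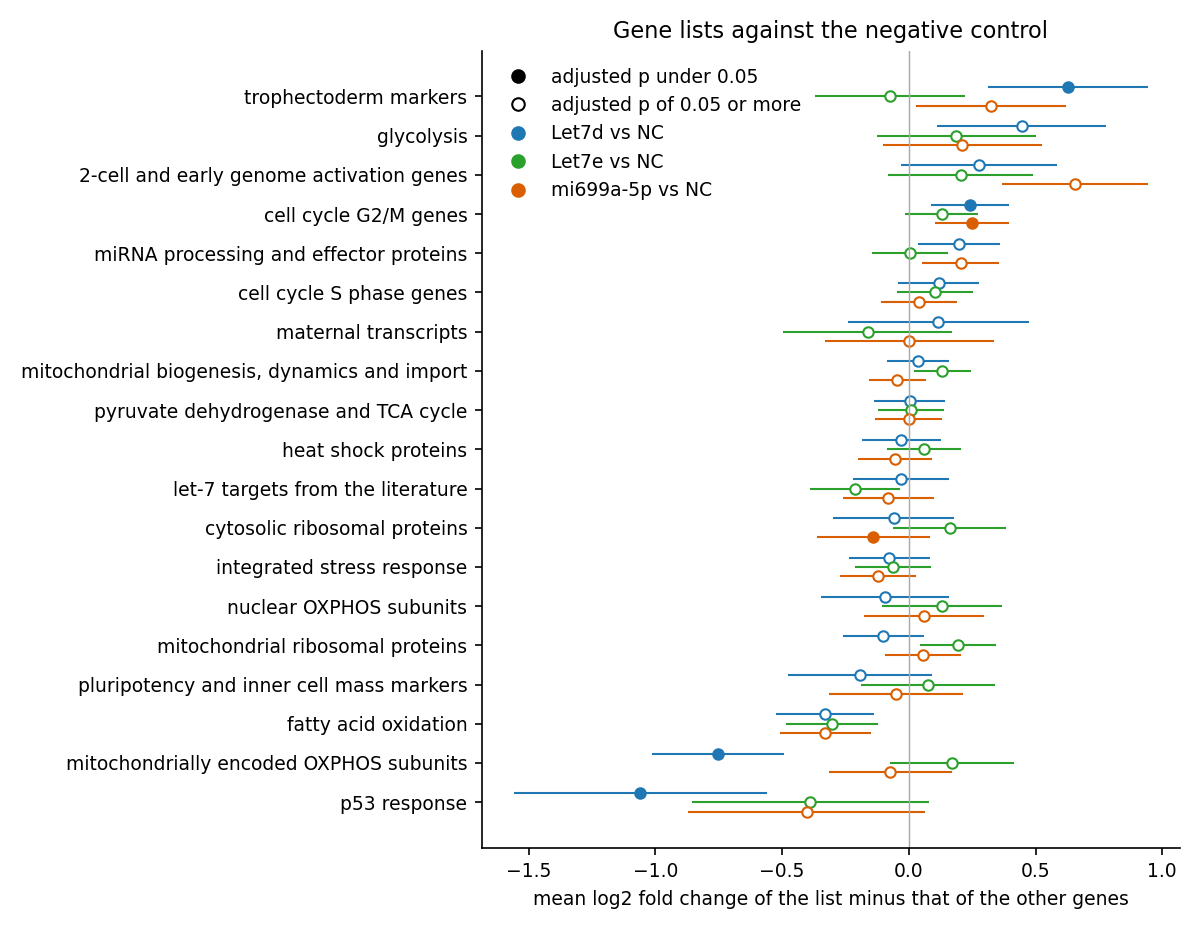
Mean log2 fold change of each gene list minus that of the other genes (x axis, ± SE) in Let7d, Let7e and mi699a-5p against NC; filled points have a camera adjusted p under 0.05 at the preset correlation. In Let7d the p53 response (-1.06) and mitochondrially encoded OXPHOS subunits (-0.75) lie farthest below 0.

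In Let7e against NC no list was called and 0 genes changed by edgeR, with 317 genes at an unadjusted p under 0.05 and 0 by DESeq2. Hmga2, a chromatin protein gene and textbook let-7 target whose 3' UTR holds 7 seed matches (chromosome 10, 120361275 to 120476469), had 233 CPM in NC and 126 CPM in Let7e. Its log2 fold change was -0.88 ± 0.30 and lower in 4 of 4 mouse ids (edgeR p = 0.0078, adjusted p = 0.999). Tnrc6a, whose protein links Argonaute to deadenylation, gave -1.39 ± 0.37 and was the only one of 21 miRNA processing and effector genes to change when adjusted over the list alone (adjusted p = 0.0275). Over all genes the lowest edgeR adjusted p in this comparison was 0.999. Of 25 let-7 targets 18 lay below 0, with a list effect of -0.21 ± 0.18 (camera adjusted p = 0.413), and Nras (0.57 ± 0.31) and Ccnd2 (1.83 ± 0.99) lay above it. The smallest p belonged to Htr5b (-2.79 ± 0.64), Prdx6, a peroxiredoxin gene (-0.83 ± 0.20), Cers6, a ceramide synthase gene (-2.63 ± 0.65), the kinase subunit gene Prkacb (1.47 ± 0.37), the exportin gene Xpo1 (0.78 ± 0.21) and Eif4b (0.76 ± 0.21). Mitochondrially encoded OXPHOS genes gave 0.17 ± 0.24 (camera adjusted p = 0.873), nuclear OXPHOS genes 0.13 ± 0.24 and mitochondrial ribosomal protein genes 0.20 ± 0.15 (adjusted p = 0.335). The p53 response gave -0.39 ± 0.47, with 14 of 17 below 0 (camera adjusted p = 0.335). Single members of metabolic lists with small p were Idh3a (-1.15 ± 0.41), a TCA cycle enzyme gene, and Aldoa (0.95 ± 0.33), a glycolytic one, and Klf2 (1.16 ± 0.40), Gata3 (-2.31 ± 0.89) and Cldn4 (-1.26 ± 0.52) among lineage markers.

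In mi699a-5p against NC, cytosolic ribosomal protein genes decreased by 0.14 ± 0.22, with 65 of 79 below 0 (52 of 79 by edgeR; camera, adjusted p = 0.016, and adjusted p = 0.953 with an estimated correlation). Rps2 gave -0.47 ± 0.20, Rpl8 -0.36 ± 0.18 and Rplp0 -0.32 ± 0.16. G2/M genes rose by 0.25 ± 0.15, with 20 of 25 above 0 (camera, adjusted p = 0.016, and adjusted p = 0.767 with an estimated correlation). Kif20a gave 0.90 ± 0.31, Bub1b 0.96 ± 0.35, Cenpe 0.56 ± 0.22 and Kif11 0.59 ± 0.23. Adjusted over the list alone 0 members of either list changed. Genes of the 2-cell list gave 0.66 ± 0.29, with 8 of 10 above 0 (camera adjusted p = 0.207), among them Tdpoz1 at 1.67 ± 0.59. The pluripotency gene Pou5f1 gave -0.79 ± 0.32. Over all genes 0 changed by edgeR, with 434 at an unadjusted p under 0.05, and 6 by DESeq2 (ENSMUSG00000118642.1, Fdx1, Lin7c, Myo5b, Tug1 and Xpo1). By edgeR these had fold changes of -2.02 ± 0.36 for ENSMUSG00000118642.1, -1.52 ± 0.32 for the ferredoxin gene Fdx1, 1.04 ± 0.24 for Lin7c, 5.79 ± 1.3 for Myo5b and 0.94 ± 0.21 for Xpo1. Myo5b had 0.321 CPM in NC, so its fold change rests on few reads. Cops7a gave -0.81 ± 0.20. The ribosomal protein call ended without mi699a-5p replicate 3 (-0.04, adjusted p = 0.523) or 4 (0.01, adjusted p = 0.992) and without NC replicate 1 (-0.10, adjusted p = 0.383) or 3 (-0.11, adjusted p = 0.0637), and without mi699a-5p replicate 1 it was -0.33. With the Y-linked level as a covariate it was -0.23 (adjusted p = 1.9e-05). The G2/M call ended without mi699a-5p replicate 4 (0.19, adjusted p = 0.205) or NC replicate 1 (0.15, adjusted p = 0.383), and after thinning (0.27, adjusted p = 0.0796). With a replicate block both ended (ribosomal -0.03, adjusted p = 0.692, and G2/M 0.20, 0.17).

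Let7e and Let7d, which share a seed, were compared directly to ask whether the family members act alike. Mitochondrially encoded OXPHOS genes were higher in Let7e by 0.92 ± 0.24, with 7 of 7 above 0 (camera, adjusted p = 6.93e-07, and adjusted p = 0.392 with an estimated correlation). Adjusted over the list alone 7 of 7 changed, and 0 over all genes. Mt-Nd1 gave 1.24 ± 0.26, with 9500 CPM in Let7e and 4030 CPM in Let7d, and mt-Nd2 gave 1.0 ± 0.28. Camera at the preset correlation called 5 further lists, given with their adjusted p at an estimated correlation after a slash, where 0 of them passed. Mitochondrial ribosomal protein genes were higher by 0.30 ± 0.15 (57 of 76 above 0, camera adjusted p = 0.000641 / 0.6), nuclear OXPHOS genes by 0.23 ± 0.24 (50 of 75, 0.0399 / 0.728) and cytosolic ribosomal protein genes by 0.22 ± 0.22 (60 of 79, 0.0204 / 0.728). The p53 response was higher by 0.67 ± 0.47 (14 of 17, camera adjusted p = 0.0204 / 0.6), and trophectoderm markers were lower, at -0.70 ± 0.30 (9 of 13 below 0, 0.0327 / 0.392). With the Y-linked level as a covariate the p53 effect reversed to -0.12 (adjusted p = 0.759) and the trophectoderm call ended (-0.65, 0.0805), while the nuclear OXPHOS effect was 0.43 and the cytosolic ribosomal one 0.39 (0.36 and 0.33 with split mouse ids). Gata3 at -3.02 ± 0.91 and Lrp2 at -1.70 ± 0.53 changed when adjusted over the trophectoderm list alone. Dicer1 gave -1.04 ± 0.43 (edgeR p = 0.0269, adjusted p = 0.924). Tomm70a, which encodes a mitochondrial import receptor, gave 0.69 ± 0.21, and Klf2 1.25 ± 0.40.

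Over all genes 0 differed between Let7e and Let7d by edgeR, with 425 at an unadjusted p under 0.05, and 8 by DESeq2 (Arpc1b, Gsc, Htr5b, Mpzl1, Tcf7l2, Trim61, Tsga8 and mt-Nd1). The smallest p by edgeR belonged to mt-Nd1, Arpc1b (1.15 ± 0.25), Gsc (3.0 ± 0.75), Htr5b (-3.08 ± 0.65), Tcf7l2 (-1.68 ± 0.40) and Trim61 (-3.58 ± 0.93). The mitochondrially encoded call held without each mouse id, while without Let7e replicate 1 the mitochondrial ribosomal (0.23, adjusted p = 0.121), nuclear OXPHOS (0.14, 0.662), cytosolic ribosomal (0.19, 0.327), trophectoderm (-0.78, 0.109) and p53 (0.65, 0.0936) calls ended. Without Let7d replicate 2 the p53 effect was 0.16 (adjusted p = 0.498), the cytosolic ribosomal 0.12 (0.556), the nuclear OXPHOS 0.18 (0.370) and the trophectoderm -0.78 (0.116). Other single mouse ids that ended a call were Let7d replicate 1 for nuclear OXPHOS (0.23, adjusted p = 0.0922) and trophectoderm genes (-0.61, 0.0922), Let7e replicate 2 for trophectoderm genes (-0.63, 0.0574), and Let7d replicate 3 (0.72, 0.0607) and Let7e replicate 3 (0.52, 0.0592) for p53 genes, whose effect was 1.12 without Let7d replicate 1.

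The mean of Let7d and Let7e was compared with NC for a pooled let-7 effect. The p53 response decreased by 0.72 ± 0.42, with 17 of 17 members below 0 (14 of 17 by edgeR; camera, adjusted p = 0.000546, and adjusted p = 0.658 with an estimated correlation), and with the Y-linked level as a covariate the effect was -0.33 (adjusted p = 0.130). Mitochondrially encoded OXPHOS genes decreased by 0.29 ± 0.22, with 7 of 7 below 0 (camera, adjusted p = 0.0329, and adjusted p = 0.658 with an estimated correlation). In that average Let7d (-0.75) and Let7e (0.17) lay on opposite sides of NC. The call ended without Let7d replicate 3 (-0.19, adjusted p = 0.196), Let7e replicate 2 (-0.28, 0.0662), 3 (-0.26, 0.129) or 4 (-0.26, 0.111), or NC replicate 1 (-0.28, 0.138) or 3 (-0.22, 0.194). It also ended with a replicate block (-0.23, 0.114), the Y-linked level as a covariate (-0.22, 0.130) and split mouse ids (-0.25, 0.144). The p53 call ended without NC replicate 1 (-0.64, adjusted p = 0.0551), and without Let7d replicate 2 its effect was -0.47 and still called (0.0175). Hmga2 gave -0.71 ± 0.26 and was lower in 7 of 7 mouse ids (edgeR p = 0.0148, adjusted p = 0.999). Bub1b gave 1.14 ± 0.33, Mcm2, a replication licensing gene, 0.59 ± 0.19, and Omt2b 1.15 ± 0.46. By edgeR 1 gene changed, ENSMUSG00000118642.1 (-1.92 ± 0.31, lower in 7 of 7, adjusted p = 0.0499), with 307 genes at an unadjusted p under 0.05, and 5 by DESeq2 (this gene, Gfm1, Myo5b, Tug1 and Xpo1). Tug1 (1.07 ± 0.25), Xpo1 (0.82 ± 0.20) and Gfm1 (1.21 ± 0.29) had the smallest p upwards, and Stard4 (-1.57 ± 0.44) and CT010467.1 (-1.05 ± 0.30) the next downwards. The gene call held without Let7d replicate 2 and ended without any other single mouse id (adjusted p of at least 0.101).

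In a comparison that holds no NC libraries, against mi699a-5p, the mean of Let7d and Let7e had higher cytosolic ribosomal protein genes, by 0.19 ± 0.18 with 67 of 79 above 0 (45 of 79 by edgeR, with a median of 0.04; camera, adjusted p = 0.00819, and adjusted p = 0.921 with an estimated correlation). Rpl3 gave 0.41 ± 0.16 and Rps23 0.38 ± 0.18, while Rps4l gave -0.60 ± 0.26. The effect was 0.04 without mi699a-5p replicate 4 (adjusted p = 0.947), 0.09 without replicate 3 (0.567) and 0.38 without replicate 1, and the call also ended without Let7d replicate 3 (0.14, 0.242) or Let7e replicate 1 (0.17, 0.0600), and with a replicate block (0.14, 0.108). By edgeR 0 genes changed, with 504 at an unadjusted p under 0.05, and 11 by DESeq2 (Ankrd17, Cops7a, Dusp12, Eif2d, Fdx1, Fundc1, Klf9, Mga, Pink1, Sh3d21 and Snhg1). By edgeR the mitophagy kinase gene Pink1 gave 1.53 ± 0.33 and the mitophagy receptor gene Fundc1 -2.77 ± 0.68, with Cops7a at 0.81 ± 0.17, Eif2d at 0.98 ± 0.21, Klf9 at -1.10 ± 0.25 and Ep300 at -0.89 ± 0.22. Arg2 of the 2-cell list gave -2.41 ± 0.79 and Btg2 of the p53 list -1.33 ± 0.54.

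Of 4 let-7 pathway genes given for every comparison, edgeR called 0 in any of the 6, with Hmga2 at an unadjusted p under 0.05 in Let7e and the let-7 mean against NC and Dicer1 in Let7e against Let7d. Lin28a, the RNA-binding protein gene that blocks let-7 maturation, gave 0.25 ± 0.39 in Let7d, -0.15 ± 0.37 in Let7e and -0.30 ± 0.36 in mi699a-5p. Trim71 gave 0.22 ± 0.37, -0.45 ± 0.35 and 0.06 ± 0.35, and Dicer1, which encodes the nuclease that cuts microRNA precursors, 0.50 ± 0.47, -0.55 ± 0.43 and -0.06 ± 0.44. Hmga2 in Let7d gave -0.53 ± 0.32 (edgeR p = 0.114) and in mi699a-5p -0.36 ± 0.30 (p = 0.235). For the let-7 targets in Let7d the median of 0.01 and the list effect of -0.03 differ in sign (camera adjusted p = 0.914), and 0 of 25 changed.

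**Figure D3:**
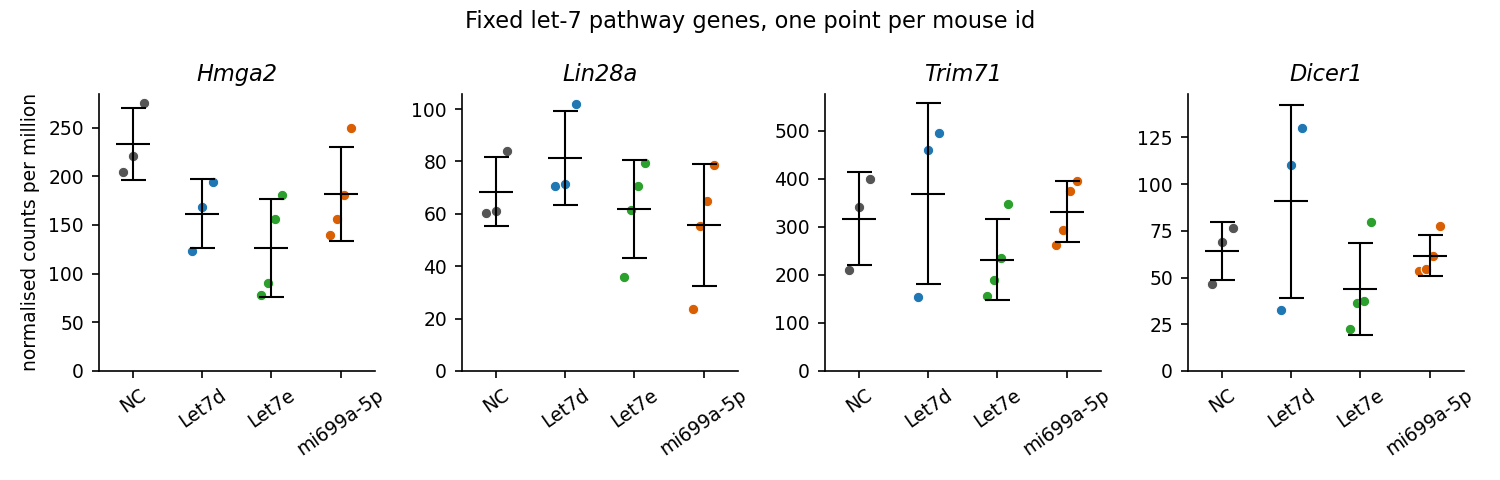
Normalised CPM (y axes, from 0) of Hmga2, Lin28a, Trim71 and Dicer1 by injected group (x axis), one point per mouse id with the group mean and SD. Mean Hmga2 was 233 in NC, 162 in Let7d, 126 in Let7e and 181 in mi699a-5p.

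Genes with a let-7 seed match in the 3' UTR were tested because repression by an injected let-7 would lower them as a class. The 1285 genes with a site differed from genes without by 0.06 ± 0.04 in Let7d (camera p = 0.26), 0.003 ± 0.039 in Let7e (p = 0.908) and 0.07 ± 0.04 in mi699a-5p (p = 0.229). Between Let7e and Let7d the difference was -0.06 (p = 0.321), for the let-7 mean against NC 0.03 (p = 0.448) and against mi699a-5p -0.04 (p = 0.512). Matched for UTR length and expression, the score was 0.0023 ± 0.0313 (SD, n = 7) in the let-7 mouse ids and -0.0023 ± 0.0407 (n = 7) in NC and mi699a-5p. The difference of 0.0046 log2 had an exact permutation p of 0.81 and a 95% interval from -0.0371 to 0.0452. For the 286 genes with an 8mer it was -0.0155, with an interval from -0.0951 to 0.0599.

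**Figure D4:**
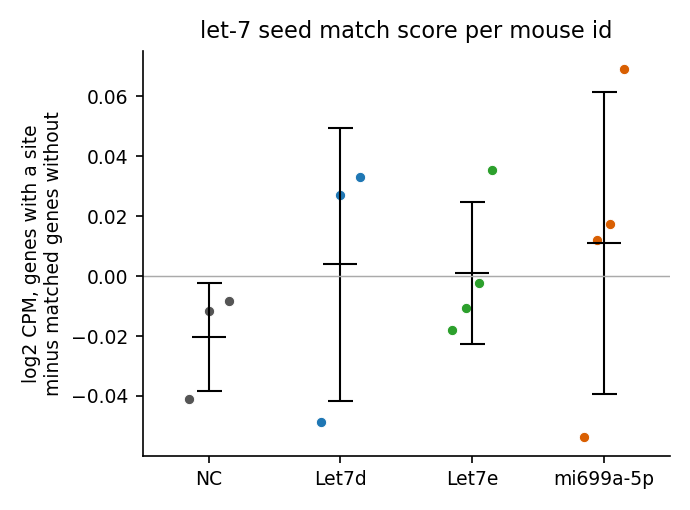
Score of genes with a let-7 site (log2 CPM minus that of genes without a site matched for UTR length and expression, y axis) by injected group (x axis), one point per mouse id with the group mean and SD. The group means lie between -0.0203 in NC and 0.0112 in mi699a-5p.

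Fold changes of Let7d and Let7e against NC were compared across genes, which are not independent replicates and share the NC libraries. They had r = 0.44, against 0.42 ± 0.01 (SD) for simulated unchanged groups set against the same NC libraries. Genes were simulated independently of each other, so the spread and the highest values of the simulations can be too narrow. Simulated groups were drawn around the mean of all libraries, NC included. That moves them towards the real NC libraries, so correlations and shared counts simulated against these can be too low. Upwards 62 genes had an unadjusted p under 0.05 in both (50.2 in the simulations, 4.88 from the product of the counts), and downwards 19 (12.1 and 2.72). None of these was past the threshold in both, and 0 went in opposite directions. Let7d and mi699a-5p gave r = 0.49, against 0.42 simulated, and Let7e and mi699a-5p 0.48 against 0.46. With the NC libraries simulated too, the 3 pairs gave 0.54, 0.53 and 0.58, above the observed values. Let7d and mi699a-5p shared 82 genes upwards and 24 downwards, above the highest of the simulations against the same NC libraries (69 and 18), while with NC simulated too the highest were 81 and 43. NC embryos were injected as well. The 3 NC mouse ids could not be divided into groups of 2 or more, so shared NC libraries and shared effects of the injected microRNAs were not separated. Nor was the number of Xist-carrying cells, which was 13 of 18 in Let7d, 4 of 20 in Let7e, 9 of 21 in mi699a-5p and 4 of 22 in NC.

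The remaining lists were not called in the 6 comparisons. Against NC, fatty acid oxidation genes gave -0.33 ± 0.19 in Let7d, -0.30 ± 0.18 in Let7e and -0.33 ± 0.18 in mi699a-5p (camera adjusted p = 0.237, 0.335 and 0.507). Glycolysis gave 0.45 ± 0.33, 0.19 ± 0.31 and 0.21 ± 0.31, pyruvate dehydrogenase and the TCA cycle 0.004 ± 0.140, 0.008 ± 0.131 and -0.0007 ± 0.1310, and mitochondrial biogenesis, dynamics and import 0.04 ± 0.12, 0.13 ± 0.11 and -0.05 ± 0.11. Maternal transcripts gave 0.12 ± 0.36, -0.16 ± 0.33 and 0.002 ± 0.334, 2-cell genes 0.28 ± 0.31 and 0.20 ± 0.29 in Let7d and Let7e, and pluripotency markers -0.19 ± 0.28, 0.08 ± 0.27 and -0.05 ± 0.27. S phase genes gave 0.12 ± 0.16, 0.10 ± 0.15 and 0.04 ± 0.15, the integrated stress response -0.08 ± 0.16, -0.06 ± 0.15 and -0.12 ± 0.15, heat shock proteins -0.03 ± 0.16, 0.06 ± 0.15 and -0.05 ± 0.15, and miRNA processing genes 0.20 ± 0.16, 0.005 ± 0.151 and 0.21 ± 0.15. The interferon list had 3 measured genes, with summed levels of 105 CPM in NC, 106 in Let7d, 98.5 in Let7e and 98.2 in mi699a-5p. Of the sperm list only Odf2 was measured (33.8, 38.5, 26.2 and 31.1 CPM), of the Y-linked list 4 genes (141, 52.4, 144 and 78.8 CPM), and of the cumulus and granulosa list and the blood, skin and stromal list 0.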

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

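Of the tests in this part, the ribosomal RNA share, the Y-carrying Let7d mouse id, the mitochondrially encoded list under the Y-linked covariate, the depth trend within mouse ids, cells with both transcripts, and p53 scores over whole mouse ids were chosen after the result was seen. One mouse id lay far from its group: the correlation between blastomeres was 0.119 in 1 Let7e mouse id, in 1 of 52 groups of 4 examined, where chance gives about 1 in 20. In a direct test of Let7e against Let7d, camera called 6 lists at the preset correlation, 0 with an estimated correlation, and fry called 0. The 6 were mitochondrially encoded OXPHOS subunits (0.92 log2, Let7e minus Let7d), mitochondrial ribosomal proteins (0.30), nuclear OXPHOS subunits (0.23), cytosolic ribosomal proteins (0.22), p53 response (0.67) and trophectoderm markers (-0.70). With the Y-linked level as a covariate the p53 difference reversed to -0.12 and the trophectoderm call ended (-0.65, adjusted p = 0.0805 by camera).

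The lower mitochondrially encoded share of Let7d (2.4% against 3.82% in NC) was weighed against ribosomal RNA, depth and sex. Ribosomal RNA genes took less of the Let7d reads, by -6.93 percentage points, so they did not crowd out other transcripts. CT010467.1 alone gave -6.07 (exact permutation p = 0.2), while mt-Rnr1 and mt-Rnr2 are themselves mitochondrially encoded. The trend of the share on depth among cells of one mouse id gives -0.0888 percentage points for the Let7d depth, or -0.574 with 2 standard errors added. That is less than 0.5 of the observed gap, which argues against depth as the main cause. Thinning kept 90.9% of the difference, but thinning leaves the expected share of a gene as it was, so this value decides nothing although it met the bound written for it. With the Y-linked level as a covariate the list stayed called at -0.62 ± 0.31 (from -0.75; camera adjusted p = 0.00147, over the 8 alternatives up to 0.335), which met the bound written for it. This does not decide whether sex is the whole cause, since the call rests on the preset correlation. The covariate is also a log2 level, which does not follow the share of Xist-carrying cells in a mixed mouse id. Sex stays open as a cause. The 1 Let7d mouse id with Y-carrying cells had 2.60%, below every NC mouse id, where 1 library decides nothing. In each of the 3 mouse ids with both kinds the share was lower in Xist-carrying than in Y-carrying cells, without a test. It was 5.77% against 6.12% in Let7e replicate 1, 3.12% against 3.73% in NC replicate 2 and 2.61% against 3.33% in mi699a-5p replicate 4. The list score of Xist-carrying minus Y-carrying cells in these gave 0.05, -0.16 and -0.86, the last with 1 Y-carrying cell. A batch that coincides with the groups was not weighed and cannot be told apart from let-7d. An effect of let-7d is a hypothesis.

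Both Xist-carrying and Y-carrying cells occurred in Let7e replicate 1, mi699a-5p replicate 4 and NC replicate 2. In these mouse ids 0 cells reached both thresholds, 50 CPM of Xist and 20 CPM of Y-linked genes. That argues against RNA mixed between cells at such levels. Mixing below the thresholds stays open. Of the 2 Y-carrying cells of Let7e replicate 1, 1 had 12.4 CPM of Xist beside 176 CPM of Y-linked genes, and the other had 0 CPM of Xist. Outside chromosomes X and Y, cells of one kind correlated more than cells of different kinds in 3 of 3, by 0.088, 0.044 and 0.129. This is consistent with blastomeres of more than 1 embryo under 1 mouse id. No biological explanation was tested.

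The lower p53 response of Let7d (-1.06) was weighed against the sex of the embryos, as 2 of 3 Let7d mouse ids held Xist-carrying cells alone. Within the 3 mouse ids with both kinds, the score of Xist-carrying minus Y-carrying cells was -1.96, -1.64 and -0.41, with a mean of -1.33 ± 0.47 (SE), by a test written before that value was seen. Over whole mouse ids the 3 with Xist-carrying cells alone averaged -1.49 ± 0.56 (SD) and the 8 with Y-carrying and no Xist-carrying cells -0.16 ± 0.32, 1 of which held 1 cell that carried neither. That difference, -1.33 (exact permutation p = 0.0121, the smallest possible), decides nothing, since 2 of the 3 are the Let7d values in question and the scores had prompted the comparison. From the cells within mouse ids alone, sex of the embryos may account for the p53 difference in Let7d, though the kinds may also be different embryos, mi699a-5p replicate 4 has 1 Y-carrying cell, and an effect of let-7d stays open.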

How the results depend on the processing

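Splitting mouse ids that hold both kinds of cells and leaving out ribosomal RNA genes were chosen after the results were seen. A value without a call counted as the same if it stayed without one and its sign held or it moved by less than 1 standard error (1 SD for quality measures). The seed match set, which was not called in any comparison, was the same by this rule in 108 of 108 values. That count does not show that its direction held. Of 11026 values for named genes 10878 were the same by that rule, 101 moved, 21 passed the threshold anew and 26 no longer did. Nearly all named genes had no call to lose. The only one called, ENSMUSG00000118642.1, kept its call in Let7d against NC in 5 of 11 other settings and 2 of 6 without single mouse ids. For the let-7 mean against NC it kept its call in 4 of 11 and 1 of 10. Of 1728 for lists other than the mitochondrially encoded one 1628 were the same, and of 324 for quality measures 311. The filter on low counts and the filter on cells removed 0 genes and 0 cells, so they test nothing.

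Genes changed in Let7d against NC were 0, from 1, with a replicate block, only the groups compared, thinning, the Y-linked covariate, limma on RPKM, split mouse ids or ribosomal RNA genes left out. That last alternative also left out the called gene, ENSMUSG00000118642.1, although nothing in the annotation makes it ribosomal RNA, so its count of 0 follows from its construction. The count of 0 by limma on RPKM, here and for the let-7 mean against NC, says nothing either. RPKM values of one gene are not on one scale between cells. For the let-7 mean against NC they were 0, from 1, with RLE normalization, a replicate block, thinning, the Y-linked covariate, only mouse ids of at least 7 labelled cells, limma on RPKM, split mouse ids or ribosomal RNA genes left out. DESeq2 gave 3 for Let7d, 6 for mi699a-5p, 5 for the let-7 mean against NC, 8 for Let7e against Let7d and 11 for the let-7 mean against mi699a-5p. Without single mouse ids the counts ranged from 0 to 1 for Let7d, the let-7 mean against NC and Let7e against Let7d, and from 0 to 2 for mi699a-5p. For the other alternatives the cause was not tested.

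Lists called with a replicate block were 4 for Let7d, 2 for Let7e, 0 for mi699a-5p, 7 for Let7e against Let7d, 1 for the let-7 mean against NC and 2 for the let-7 mean against mi699a-5p. The numbers of mouse ids do not pair them, since same-numbered ones had a mean correlation of 0.006. Thinning, which also left out 6 mi699a-5p and 2 NC cells below the depth and 0 of Let7d and Let7e, gave 7 lists for Let7d and 1 for mi699a-5p. The Y-linked covariate gave 5 for Let7d, 4 for Let7e against Let7d and 0 for the let-7 mean against NC. Split mouse ids gave 2 for Let7d, 2 for Let7e and 1 for the let-7 mean against NC. Camera with an estimated correlation and fry each called 0 lists in Let7d, mi699a-5p, Let7e against Let7d and the let-7 mean against NC and against mi699a-5p, where the preset correlation called 4, 2, 6, 2 and 1. Without single mouse ids the counts ranged from 2 to 7 for Let7d, 0 to 2 for mi699a-5p, 1 to 6 for Let7e against Let7d, 0 to 4 for the let-7 mean against NC and 0 to 2 for the let-7 mean against mi699a-5p. The cause was not tested.

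The mitochondrially encoded list stayed called in Let7d against NC without each of 6 mouse ids (-0.88 to -0.55) and in Let7e against Let7d without each of 7 (0.72 to 1.05), and in 6 of 8 other settings for each. With an estimated correlation the effects, -0.75 and 0.92, and -0.29 for the let-7 mean, did not pass. The list did not pass in these comparisons with fry either, which tests its members against no change. The let-7 mean effect also did not pass with a replicate block (-0.23), the Y-linked covariate (-0.22) or split mouse ids (-0.25), and ranged from -0.37 to -0.19 without single mouse ids. Reversed were the p53 response in Let7e against Let7d with the Y-linked covariate (-0.12, from 0.67; adjusted p = 0.759 by camera, over settings 0.0146 to 0.759) and cytosolic ribosomal proteins in mi699a-5p without mi699a-5p replicate 4 (0.0143, from -0.14; range -0.33 to 0.0143). The cause was not tested.

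The number of mouse ids and the spread between them limit what can be called: in simulated data with 3 against 3 mouse ids edgeR recovered 8.6% of genes changed 2-fold and 47.8% of those changed 4-fold, so changes of that size can go without a call.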

Other observations

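The tests of other splits for lists, and the comparison of lists between kinds of cells, were chosen after results were seen. Xist-carrying minus Y-carrying cells of the same mouse id were scored for 19 lists over 3 mouse ids, without a test. The values given here were picked from them after they were seen. The 2-cell genes gave 0.91 ± 0.07 (SE), above 0 in 3 of 3, maternal transcripts 0.80 ± 0.27, glycolysis -0.76 ± 0.21 and let-7 targets -0.23 ± 0.04, while mitochondrially encoded OXPHOS genes gave -0.33 ± 0.28. In mi699a-5p replicate 4, which has 1 Y-carrying cell, maternal transcripts gave 1.33, against 0.52 in Let7e replicate 1 and 0.54 in NC replicate 2, and mitochondrially encoded genes -0.86, against 0.05 and -0.16, so the size of both means depends on that mouse id. The cells may come from different embryos, as the correlation was 0.044 to 0.129 higher within a kind.

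Some genes lay on the same side of NC in each group injected with a microRNA. Tug1 averaged 206 CPM in NC and 505, 374 and 455 CPM in Let7d, Let7e and mi699a-5p, Xpo1 545 against 986, 937 and 1050, Gfm1 58.8 against 144, 127 and 134, and ENSMUSG00000118642.1 197 against 31.3, 86.2 and 48.8. These were chosen after their values were seen, and the same NC mouse ids enter each comparison. ENSMUSG00000118642.1 and the ribosomal RNA gene CT010467.1 had r = 0.562 over 14 mouse ids, which was 0.178 without the 2 farthest. As deviations from the group means they had r = 0.202 (resampled permutation p = 0.487), and 0.354 without the 2 farthest.

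The hypothesis that injected let-7 lowers transcripts with a seed match as a class was tested with a bound of -0.05 log2 written beforehand. The lower end of the 95% interval was -0.0371, above that bound, so a shift of the class beyond that bound was not seen over the 7 against 7 mouse ids. The bound does not hold for every form of the test: the interval was -0.0648 to 0.044 for the let-7 mean against mi699a-5p, and -0.0951 to 0.0599 for 8mer sites over the 7 against 7, so a shift of that size in 8mer genes and effects on single targets such as Hmga2 stay open. Without matching the difference was -0.0142 (exact permutation p = 0.67, interval -0.0829 to 0.0517), so whether UTR length or expression could hide a shift cannot be told apart, as neither difference was called.

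Other splits of the mouse ids were counted for each comparison. For Let7d against NC 10 splits are too few for a share under 0.05: the real split gave 1 gene and 4 lists, the highest other 1 and 4, and 2 splits reached each. Where the real count was 0, any split reaches it and the count of splits says nothing: this holds for the genes and lists of Let7e against NC (35 of 35, highest other 4 and 7), and for the genes of mi699a-5p against NC (35 of 35, highest other 1), Let7e against Let7d (35 of 35, highest other 4) and the let-7 mean against mi699a-5p (100 of 100 drawn from 330, highest other 1). As many lists as the real split were called in 25 of 35 for mi699a-5p (real 2, highest other 6), 2 of 35 for Let7e against Let7d (real 6, highest other 6), 53 of 100 drawn from 120 for the let-7 mean against NC (real 2, highest other 8) and 84 of 100 for the let-7 mean against mi699a-5p (real 1, highest other 6). As many genes were called in 8 of 100 for the let-7 mean against NC (real 1, highest other 2). For these 5 counts chance can not be excluded. Some splits call several times as many lists as the real one, which may come from a structure among the mouse ids or from correlation between list members above the preset, as an estimated correlation left 0 lists called in each comparison. These were not told apart.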
